A study of Danio rerio with 12 samples.

How the data were processed

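RNA was measured in 12 libraries of EGFP-positive cells sorted from zebrafish neuroblastomas, 4 from tumours driven by a MYCN transgene and 8 from tumours driven by a MYC transgene. Per the labels, tumours were broken up mechanically, the fluorescent cells were sorted, and their RNA was extracted with Trizol-LS, depleted of ribosomal RNA and sequenced as paired 100 bp reads. The deposited table gives 1 FPKM value (fragments scaled by transcript length and by the depth of the library) per gene and library for 14581 genes. The values do not show which measure of depth was used. The authors named cutadapt, TopHat2 2.0.11 and Cufflinks 2.2.1 in their processing notes. The genome build and annotation behind the values were not given in the sources used here. The table used here held FPKM values without fold changes or p-values, so no test of the authors was compared.

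The depth in reads is unknown, because FPKM carries no fragment count. Low values gave no shared step that would mark 1 fragment: over the 66 pairs of libraries, the fullest bin of the ratios between values under 0.5 FPKM (bins of 0.1 on the log2 scale) held 2.84% to 12.6% of the genes. No counting interval was therefore given, and precision rests on the spread between libraries. In the table, 705 genes were listed at 0 in all 12 libraries and 10819 were above 0 in all of them. Among the 705 was the elongation factor gene eef1a1l1, so a 0 in all 12 libraries need not mean no expression. In addition, 10 gene names had been turned into dates and could not be matched to the lists. Genes that share reads with near-identical copies (such as eef1a1b and eef1a1l2, or the keratins) have uncertain values, since the handling of such reads was not given.

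Genes with at least 1 FPKM in at least 4 of the 12 libraries were tested, which left 9606 genes. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), MYC minus MYCN, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are therefore on the scale of FPKM + 1 and understate ratios of genes near 0. A positive log2 fold change means higher in MYC. The words "rose" and "fell" stand for higher and lower in MYC with the adjusted p under 0.05. Errors are SE for fold changes and SD for FPKM, with n = 4 MYCN and 8 MYC libraries. The labels do not say whether replicates came from separate fish, so the p-values measure the spread between these samples, whatever its source.

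A set of 39 gene lists was fixed, covering growth programmes, sympathoadrenal identity, the retinoic acid pathway and markers of other cell types that a sort could hold. The lists held 1320 symbols, of which 1102 were matched to the table, 109 of them under another name. Lists with at least 4 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes and adjustment over the 36 lists tested. The cholinergic list (2 of 5 measured members tested) and the endothelial list (3 of 20) were too short, and no transcript of the mitochondrial genome was measured. Beside each called list stand the counts of members that rose, fell or did not pass over all genes tested. With them stand the counts adjusted over the list alone and the result with a correlation estimated from the data. Lists that were not called are given more briefly. With an estimated correlation none of the 36 lists was called. The fry rotation test and an exact permutation of the mean standardised value per library were run as alternatives.

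The tests, the lists, the filter and the naming rule were chosen before the data were examined. Genes are named when they were among the 12 with the highest or the 12 with the lowest log2 fold change (called, a mean of at least 5 FPKM in the higher group, and not a provisional symbol), among the 4 members of a described list with the smallest p, or among a short list of sympathoadrenal, MYC family and retinoic acid genes. Other names are said to be chosen after their values were seen.

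Replicate numbers were checked for pairing. For replicates 1 to 4 the deviations from the group mean correlated between the MYCN and the MYC library of the same number across genes at 0.249, 0.379, 0.535 and 0.149, all above the preset limit of 0.1, and 3 of the 4 MYCN libraries correlated best with their own number. Genes are not independent replicates, and the labels do not say what the numbers stand for. A fit with the replicate number as a block over these 8 libraries was therefore given where it changed a call.

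The zeros in the table split the libraries into 3 sets of 4: MYCN 1 to 4, MYC 1 to 4 and MYC 5 to 8. Because the MYCN libraries all lie in a set of their own, the set and the genotype cannot be fully separated, and values were also computed for MYCN against each MYC set.

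Alternatives covered the pseudocount, the filter, the scaling between libraries, library weights, the replicate block, the test, and leaving out each library in turn. The alternatives chosen after seeing the data were the fits without genes listed at 0 in a set, MYCN against MYC 5 to 8, a 3-group fit, and the fit without MYCN 3, MYC 3 and MYC 7. Tested on simulated data with independent genes, the same fit recovered changes of known size, with the list test finding a shifted list and no other. Members of the real lists move together (estimated correlation 0.809 for cytosolic ribosomal proteins). The simulation therefore cannot say how often the list test calls wrongly here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.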

Results

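EGFP-positive tumour cells from zebrafish neuroblastomas were compared between 2 transgenic models, with 4 MYCN and 8 MYC libraries. The series labels frame the comparison as the difference between MYC-driven and MYCN-driven disease and mention resistance to retinoic acid, a differentiating drug in neuroblastoma care. The FPKM of all genes summed, in units of 1000 FPKM, to 747 ± 110 per MYCN library (SD, range 610 to 867) and 861 ± 175 per MYC library (range 567 to 1058). The depth in reads is unknown. On average 9129.5 genes per MYCN library and 9147.5 per MYC library reached 1 FPKM, and the 10 most abundant genes held 11.6% and 12.7% of the sum. The dopamine beta-hydroxylase gene dbh, a marker of noradrenergic cells, stood at 2499 ± 632 FPKM in MYCN and 1803 ± 548 FPKM in MYC libraries (adjusted p = 0.269). The tyrosine hydroxylase gene th, which starts catecholamine synthesis, stood at 646 ± 217 and 518 ± 182 FPKM (adjusted p = 0.510).

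The MYC cells had far less RNA of several developmental genes than the MYCN cells. The gene ascl1a, a proneural factor of sympathetic progenitors, fell from 63.5 ± 31.8 FPKM in MYCN (SD, n = 4) to 2.27 ± 3.04 FPKM in MYC (n = 8), a log2 fold change of -4.68 ± 0.59 (SE, adjusted p = 0.000202). The gene ret, a receptor for glial-derived neurotrophic factors, fell from 32.4 ± 6.79 to 3.47 ± 1.55 FPKM (log2 fold change -2.96 ± 0.29, adjusted p = 2.0e-05). In the other direction, the glycolytic enolase gene eno2 rose from 21.1 ± 2.75 to 83.0 ± 26.1 FPKM (1.86 ± 0.25, adjusted p = 0.000392). The complement gene c1qb, made by macrophages, rose from 8.95 ± 5.13 to 71.5 ± 44.3 FPKM (2.81 ± 0.45, adjusted p = 0.00133).

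Of the 16 tested sympathoadrenal transcription factors, 9 fell, 1 rose and 6 did not pass, with the same counts adjusted over the list alone. The sympathoadrenal median was -1.03, and -0.39 with no filter (adjusted p = 0.000443, adjusted p = 0.651 with an estimated correlation). Besides ascl1a, isl1, a LIM homeodomain factor of sympathetic neurons, fell from 44.8 ± 23.2 to 5.6 ± 4.46 FPKM (-2.99 ± 0.50, adjusted p = 0.00176). So did sox11b, a factor of immature neurons (-1.80 ± 0.33, adjusted p = 0.00323). The 1 that rose was meis2a, a homeodomain cofactor, from 4.93 to 23.2 FPKM (2.44 ± 0.44, adjusted p = 0.00284). Among the core factors of noradrenergic identity, phox2bb went from 46.2 ± 29.4 to 9.27 ± 7.88 FPKM (-2.21 ± 0.53, adjusted p = 0.0140). The factor hand2 went from 2569 ± 748 to 1242 ± 320 FPKM (-1.04 ± 0.26, adjusted p = 0.0184). The phox2bb call ended without MYCN 1 (adjusted p = 0.0526) or MYCN 2 (0.0601). That of hand2 ended without MYCN 1 (0.0570), MYCN 2 (0.0739) or MYCN 4 (0.0634). Against MYC 5 to 8 alone neither was called (0.0942 and 0.0876), nor was hand2 against MYC 1 to 4 (0.0664). The log2 fold changes against MYC 1 to 4 and MYC 5 to 8 were -2.28 and -2.13 for phox2bb and -1.03 and -1.04 for hand2. For phox2a the log2 fold change was -0.84 ± 0.36 (adjusted p = 0.146, and 0.0279 with the replicate block). For gata3 the levels were 218 and 152 FPKM (adjusted p = 0.397). Of the 13 catecholamine synthesis and transport genes 1 rose and none fell, and neither direction had a call adjusted over the list alone (list adjusted p = 0.203).

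Of the 22 neuronal and neuroendocrine genes, 5 fell, 1 rose and 16 did not pass, and 9 fell and 1 rose adjusted over the list alone. The neuronal median was -0.51 (adjusted p = 0.0312, adjusted p = 0.651 with an estimated correlation). The adhesion molecule nadl1.2, a fish L1CAM, fell from 30.7 to 5.70 FPKM (-2.21 ± 0.23, adjusted p = 4.24e-05). The gene stmn2b, a microtubule regulator of growing axons, fell by 1.29 ± 0.18 on the log2 scale (adjusted p = 0.000438). The 1 that rose was scg2b, a granin of secretory granules, from 9.87 ± 5.85 to 157 ± 89 FPKM (3.81 ± 0.48, adjusted p = 0.000228). This list's call ended without MYCN 4 (adjusted p = 0.0568) or MYC 7 (0.0691), with the replicate block (0.0971) and under each of the 3 other scalings (median-ratio 0.126, quantile 0.0605, common sum 0.0525). Its median was -0.27 without MYCN 1, -0.26 without MYC 7 and -0.14 with no filter. Of the 6 neural crest progenitor genes, 2 fell (list adjusted p = 0.0563). The list's adjusted p was 0.651 with an estimated correlation and 0.200 by exact permutation of its score. The list was called without MYCN 4 (0.0359) or MYC 4 (0.0458), after median-ratio scaling (0.0479) or rescaling to a common sum (0.0499), against MYC 5 to 8 (0.0317) and by fry. The first was tfap2a, an early neural crest factor, which fell from 259 to 98.0 FPKM (-1.36 ± 0.29, adjusted p = 0.00715). The other was mitfa, the master factor of melanocytes, which fell from 34.5 ± 12.1 to 0.0588 ± 0.0488 FPKM (-5.01 ± 0.20, adjusted p = 9.96e-10).

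**Figure D1:**
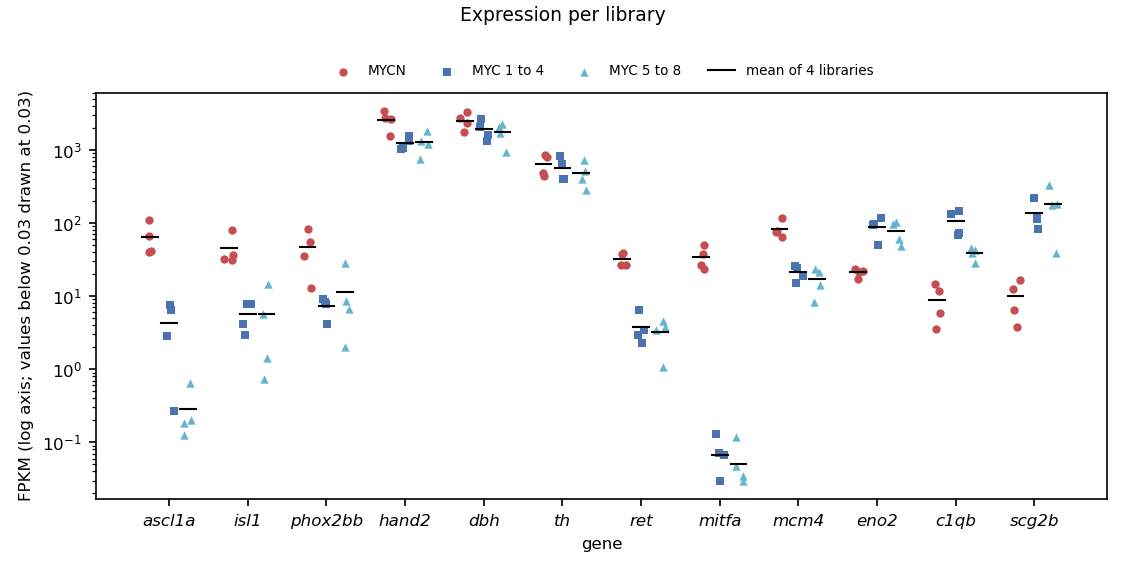
FPKM of 12 named genes in each library on a log axis, with bars at the mean of the 4 libraries of each set and values under 0.03 FPKM drawn at 0.03. For mitfa, ascl1a and ret every MYCN library lies above every MYC library, while th and dbh overlap between the groups.

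Of the 23 glycolysis genes, 10 rose, 2 fell and 11 did not pass, and 12 rose and 2 fell adjusted over the list alone. The glycolysis median was 0.65 (adjusted p = 1.50e-06, adjusted p = 0.369 with an estimated correlation). The phosphoglycerate kinase gene pgk1 rose from 127 ± 29.3 to 342 ± 82.9 FPKM (1.41 ± 0.23, adjusted p = 0.00137). The triosephosphate isomerase gene tpi1b rose from 139 to 408 FPKM (1.52 ± 0.26, adjusted p = 0.00202). The 2 that fell are transporters. The gene si:ch211-105j21.7, also known as the monocarboxylate transporter slc16a1a, fell from 2.37 to 0.257 FPKM (-1.43 ± 0.24, adjusted p = 0.00191). The glucose transporter gene slc2a1a fell by 1.67, and was named after its value was seen.

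Of the 60 ribosome biogenesis genes, 5 rose, none fell and 55 did not pass, and 1 rose adjusted over the list alone. The ribosome biogenesis median was 0.38, and 0.20 after rescaling to a common sum (adjusted p = 1.02e-05, adjusted p = 0.651 with an estimated correlation). The processome component cirh1a, also known as utp4, rose from 45.3 to 96.2 FPKM (1.04 ± 0.23, adjusted p = 0.00884). The gene ltv1, which helps export the small subunit, rose by 1.11 ± 0.31 on the log2 scale (adjusted p = 0.0281). The call of ltv1 ended without any 1 of the 4 MYCN libraries (adjusted p = 0.0546 to 0.0781). Of the 83 cytosolic ribosomal proteins, only rpl3 rose, a gene listed at 0 in all MYCN libraries, and 82 did not pass, with the same counts adjusted over the list alone. The list's median was 0.22 (adjusted p = 0.0108, adjusted p = 0.837 with an estimated correlation). Its call ended without MYCN 1 (0.103) or MYCN 4 (0.198), and quantile normalisation turned its direction (adjusted p = 0.832). Its median was 0.07 without MYCN 4, 0.14 without MYC 2, 0.34 without MYCN 2 or MYC 8, 0.38 without MYC 4, and 0.03 after rescaling to a common sum. Of the 39 translation factors and aminoacyl-tRNA synthetases, 3 rose, 1 fell and 35 did not pass, and 5 rose and 1 fell adjusted over the list alone. The translation median was 0.23 (adjusted p = 0.0423, adjusted p = 0.759 with an estimated correlation). The initiation factor gene eif4g2a fell from 53.6 to 26.2 FPKM (-1.04 ± 0.21, adjusted p = 0.00468). The elongation factor gene eef1a1b rose from 0.274 to 6.14 FPKM (2.26 ± 0.45, adjusted p = 0.00496). Another elongation factor gene, eef1a1l1, was listed at 0 in all 12 libraries. This last list was not called with the replicate block (0.269), after quantile normalisation (0.360, median 0.10) or rescaling to a common sum (0.0565, median 0.04). Nor was it called without MYCN 1, MYCN 2, MYCN 4, MYC 2, MYC 5, MYC 6 or MYC 7 (0.0555 to 0.0907), with a median of 0.13 without MYC 5.

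Of the 36 DNA replication and S phase genes, 6 fell, none rose and 30 did not pass, and 10 fell adjusted over the list alone. The DNA replication median was -0.35 (adjusted p = 0.00134, adjusted p = 0.651 with an estimated correlation). The replicative helicase subunit mcm4 fell from 83.3 ± 23.7 to 18.9 ± 6.03 FPKM (-2.11 ± 0.28, adjusted p = 0.000285). Its partners mcm5 (-1.24 ± 0.24) and mcm3 (-1.17 ± 0.23) fell as well, and so did orc6 of the origin recognition complex (-1.48 ± 0.30, adjusted p = 0.00496). Of the 37 mitosis genes, 2 fell and 35 did not pass, also adjusted over the list alone. The mitosis median was -0.39 (adjusted p = 0.0371, adjusted p = 0.837 with an estimated correlation). The 2 that fell were plk4, a kinase of centriole duplication (-0.80 ± 0.20, adjusted p = 0.0167), and ect2, which drives cytokinesis (-2.12 ± 0.54, adjusted p = 0.0189). Against MYCN the mitosis median was -0.83 for MYC 5 to 8 and 0.04 for MYC 1 to 4, and its direction turned with the replicate block (adjusted p = 0.658). The mitosis call ended without MYCN 1 (0.162), MYCN 3 (0.0654), MYCN 4 (0.0568), MYC 5 (0.227), MYC 6 (0.0981) or MYC 7 (0.0691), after quantile normalisation (0.0628) and after rescaling to a common sum (0.0603). Its median was -0.24 without MYCN 1, -0.23 without MYC 5 and -0.61 without MYC 1. The calls of the genes ended without MYCN 4 (0.0706 for plk4 and 0.0759 for ect2) and, for plk4, without MYCN 2 (0.0655). The 36 nucleotide synthesis genes held 1 that rose and 1 that fell, with a median of -0.09, a mean of -0.04 and a test pointing up (adjusted p = 0.854).

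Of the 58 nuclear genes of oxidative phosphorylation, 4 rose and 54 did not pass, and 3 rose adjusted over the list alone. The oxidative phosphorylation median was 0.20 (adjusted p = 0.00149, adjusted p = 0.680 with an estimated correlation, 0.0658 with the replicate block and 0.304 after quantile normalisation). Its median was 0.06 without MYCN 4, 0.13 without MYC 6, 0.05 after quantile normalisation and 0.01 after rescaling to a common sum. It was 0.08 against MYC 1 to 4 and 0.35 against MYC 5 to 8. The Rieske iron-sulphur protein gene uqcrfs1 rose from 13.4 to 57.6 FPKM (2.45 ± 0.42, adjusted p = 0.00201). Likewise cox5b2, a subunit of cytochrome c oxidase, rose by 2.23 ± 0.44 on the log2 scale (adjusted p = 0.00473). Of the 35 p53 target and apoptosis genes, 3 rose, 1 fell and 31 did not pass, and 6 rose and 1 fell adjusted over the list alone. The p53 median was 0.44, with 0.27 without MYCN 3, 0.22 against MYC 5 to 8 and 0.28 after rescaling to a common sum (adjusted p = 0.0192, adjusted p = 0.651 with an estimated correlation). The one that fell was apaf1, the core of the apoptosome (-1.27 ± 0.28, adjusted p = 0.00865). Of those that rose, mcl1b guards against apoptosis (1.31, adjusted p = 0.0324, but 0.0517 to 0.116 without MYCN 1, MYCN 2, MYCN 4, MYC 2 or MYC 4). Of the 29 Polycomb, DNA methylation and BET regulators, 4 fell and 25 did not pass, and 9 fell and 2 rose adjusted over the list alone. The Polycomb median was -0.29 (adjusted p = 0.0270, adjusted p = 0.651 with an estimated correlation). The histone H3 lysine methyltransferase gene ezh2 fell from 7.58 to 2.61 FPKM (-1.27 ± 0.22, adjusted p = 0.00189). The gene suz12a, its partner in the Polycomb complex, fell from 34.4 to 17.4 FPKM (-0.96 ± 0.20, adjusted p = 0.00556). The Polycomb list was not called with the replicate block (0.0658) or without MYCN 2 (0.0600, median -0.19), and its median was -0.44 without MYCN 3 and -0.45 after rescaling to a common sum.

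**Figure D2:**
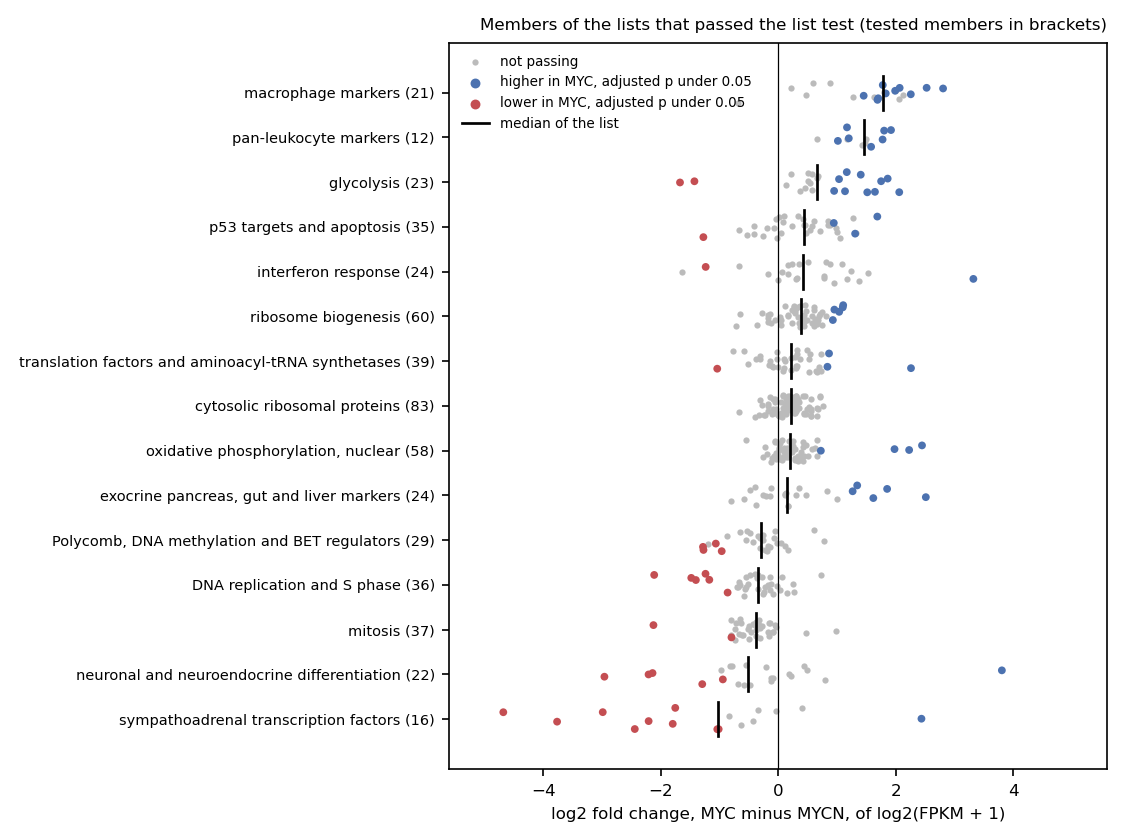
Log2 fold change (MYC minus MYCN) of each tested member of the 15 lists that passed the list test, with the list median as a black bar, members that rose in blue and members that fell in red, and genes listed at 0 in a whole set not drawn. Macrophage markers have the highest median (1.78) and sympathoadrenal transcription factors the lowest (-1.03).

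For the retinoic acid pathway, 6 of 15 tested genes fell, 1 rose and 8 did not pass, and 7 fell and 2 rose adjusted over the list alone. The list as a whole had a median of -0.48 and did not pass (adjusted p = 0.0982, and 0.651 with an estimated correlation). It was called against MYC 5 to 8 (0.0289) and with a filter of 5 FPKM (0.0221). The retinoid X receptor gene rxrga rose from 1.03 to 4.47 FPKM (1.41 ± 0.22, adjusted p = 0.000934). The gene rbp1a, a retinol-binding protein also known as rbp5, fell to 3.78 FPKM (-2.79 ± 0.60, adjusted p = 0.00796). A second retinoid X receptor gene, rxraa, fell from 8.98 to 3.25 FPKM (-1.14 ± 0.30, adjusted p = 0.0210, and 0.0685 and 0.0851 without MYCN 3 and MYCN 4). The retinoic acid carrier crabp1b fell from 34.3 to 7.78 FPKM (-2.63 ± 0.70, adjusted p = 0.0241, and 0.0657, 0.0555 and 0.0741 without MYCN 1, MYCN 3 and MYCN 4). Against MYC 1 to 4 and MYC 5 to 8 the log2 fold changes were -1.67 and -3.91 for rbp1a and -1.38 and -3.88 for crabp1b. Between the MYC sets rbp1a was called (adjusted p = 0.00197) and crabp1b was not (0.0790). The all-trans retinoic acid receptor genes named by the preset rule, raraa and rarga, had no call. The receptor gene raraa stood at 9.48 and 6.52 FPKM (-0.48 ± 0.29, adjusted p = 0.302), and rarga at 21.4 and 22.0 FPKM (adjusted p = 0.999). The retinoic acid-degrading enzyme gene cyp26a1 stayed below the filter in all libraries (0 to 0.0898 FPKM).

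The endogenous MYC family and network had 1 gene that rose and 1 that fell among 10, also adjusted over the list alone (list adjusted p = 0.781). The MYC homologue mych rose from 2.78 to 10.5 FPKM (1.45 ± 0.39, adjusted p = 0.0242, and 0.0689 and 0.0934 without MYCN 2 and MYCN 4). The MYCL gene mycla fell from 9.48 to 2.54 FPKM (-1.60 ± 0.31, adjusted p = 0.00420). Endogenous myca stood at 1.74 and 2.28 FPKM (0.23 ± 0.29, adjusted p = 0.664) and mycb at 12.9 and 3.95 FPKM (-1.60 ± 0.65, adjusted p = 0.118). For mycb the log2 fold change was -2.52 against MYC 5 to 8 (adjusted p = 0.0220) and -0.68 against MYC 1 to 4 (0.582), and it was -1.91 without MYC 3 (0.0374). Between the MYC sets themselves mycb was not called (-1.84 ± 0.44, adjusted p = 0.125). Endogenous mycn stayed below the filter (0.0759 to 1.09 FPKM), and the transgene transcripts were not analysed here.

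Markers of other cells differed between the genotypes as well, for macrophages by more in MYC 1 to 4 than in MYC 5 to 8. All 10 macrophage markers that passed were higher in MYC, of 21 tested, with 11 not passing and 17 higher adjusted over the list alone. The macrophage median was 1.78 (adjusted p = 4.48e-09, adjusted p = 0.651 with an estimated correlation). By exact permutation of the list score the list was not called (adjusted p = 0.109). Mean scores were -0.824 in MYCN, 0.916 in MYC 1 to 4 and -0.092 in MYC 5 to 8. The score of MYCN 3 (-0.0394) lay above those of MYC 5, MYC 6 and MYC 8 (-0.351 to -0.0895). Besides c1qb, spi1b, a master factor of myeloid cells, rose from 1.71 to 10.2 FPKM (1.99 ± 0.34, adjusted p = 0.00189). Similarly c1qc rose from 15.2 ± 10.3 to 90.3 ± 54.3 FPKM (2.53 ± 0.47, adjusted p = 0.00348). Of 12 pan-leukocyte markers 7 rose and none fell, and 12 rose adjusted over the list alone. The pan-leukocyte median was 1.46 (adjusted p = 4.87e-07, adjusted p = 0.557 with an estimated correlation). Among them rac2, a GTPase of blood cells, rose from 3.79 to 16.6 FPKM (1.80 ± 0.35, adjusted p = 0.00432). A substrate of protein kinase C in blood cells, plek, rose by 1.17 ± 0.28 (adjusted p = 0.0149, and 0.0538 without MYCN 4). The macrophage median was 2.38 for MYC 1 to 4 and 1.0 for MYC 5 to 8, where the pan-leukocyte median was 0.87. Of 24 interferon response genes 1 rose, 1 fell and 22 did not pass, also adjusted over the list alone. The interferon median was 0.43, and 0.79 against MYC 1 to 4 (adjusted p = 0.0270, adjusted p = 0.655 with an estimated correlation). The interferon regulator irf7 rose from 4.57 to 61.9 FPKM (3.32 ± 0.56, adjusted p = 0.00173). The class I histocompatibility gene mhc1uba fell from 38.2 to 14.2 FPKM (-1.24 ± 0.33, adjusted p = 0.0255, and 0.0854, 0.0948 and 0.102 without MYCN 1, MYCN 2 and MYCN 4). The interferon call ended without MYCN 1 (0.0514), MYCN 2 (0.248), MYCN 4 (0.0665), MYC 4 (0.0602) or MYC 7 (0.0638), against MYC 5 to 8 alone (0.365) and after quantile normalisation (0.0605). Of 24 exocrine pancreas, gut and liver markers 5 rose and 19 did not pass, also adjusted over the list alone. The exocrine median was 0.15 (adjusted p = 0.0367, adjusted p = 0.651 with an estimated correlation, 0.298 with the replicate block). The lipoprotein gene apoa1b rose from 1.32 to 11.9 FPKM (2.51 ± 0.42, adjusted p = 0.00161). The thyroid hormone carrier ttr rose by 1.27 (adjusted p = 0.0123). This list's call ended without MYCN 2 (0.166), MYC 7 (0.0870) or MYC 8 (0.0927) and after quantile normalisation (0.0605). Over the left-out libraries its median ran from 0.05 (MYC 8) to 0.30 (MYC 6), and it was 0.04 after rescaling to a common sum.

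Across single genes, the lowest log2 fold change was that of thy1, a surface glycoprotein of neurons and stromal cells, which fell from 135 ± 110 to 1.88 ± 1.29 FPKM (-5.36 ± 0.40, adjusted p = 1.35e-06). It was followed by mitfa, chodl (-4.79 ± 0.64) and the tetraspanin gene tspan7 (-4.69 ± 0.30). Next after ascl1a came tshb, a thyrotropin subunit (-4.51 ± 0.64), the opioid receptor gene oprd1b (-4.27 ± 0.31), the neural progenitor factor sox3 (-4.13 ± 0.32), the alkaline phosphatase gene alpl (-4.02 ± 0.22), the cell cycle inhibitor cdkn1c (-3.94 ± 0.33), gulp1a (-3.88 ± 0.35) and pvalb8 (-3.79 ± 0.48). Their adjusted p ran from 9.96e-10 to 0.000495. Among the highest, cox6a2, a cytochrome c oxidase subunit of muscle, rose from 27.6 ± 46.8 to 453 ± 271 FPKM (5.13 ± 0.76, adjusted p = 0.000739). Further down came scg2b, the calcium store gene casq1b (3.62 ± 0.60), pttg1ipb (3.61 ± 0.79) and olfm2b (3.59 ± 0.75). The stress-induced factor junbb (3.82 ± 1.09, adjusted p = 0.0330) ranged from 12.3 to 2460 FPKM across the MYCN libraries. Its call ended without MYCN 1 (0.122), MYCN 2 (0.0831), MYCN 3 (0.0986), MYC 2 (0.0561) or MYC 4 (0.0541), and junbb was called against neither MYC 1 to 4 (0.0510) nor MYC 5 to 8 (0.225). Without MYCN 4 its log2 fold change was 5.45 (adjusted p = 0.00043). The gene pttg1ipb was not called against MYC 1 to 4 (0.0559), nor olfm2b against MYC 5 to 8 (0.0686).

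The other 6 of the highest 12 were listed at 0 in every MYCN library, so no fold is given. In the MYC libraries the ribosomal protein gene rpl3 ranged from 3368 to 8164 FPKM, the cytoplasmic actin gene actb2 from 2082 to 6510 FPKM, phex from 1116 to 2453 FPKM, rgs5a from 689 to 3413 FPKM, mat2ab from 168 to 1020 FPKM and cst3 from 28.2 to 1797 FPKM. The other cytoplasmic actin, actb1, ranged from 1060 to 1794 FPKM in MYCN and 492 to 1448 FPKM in MYC libraries. In all, 16 genes were listed at 0 in a whole set of 4 libraries with a mean of at least 10 FPKM in another set, and 8 called genes were listed at 0 in a whole set.

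**Figure D3:**
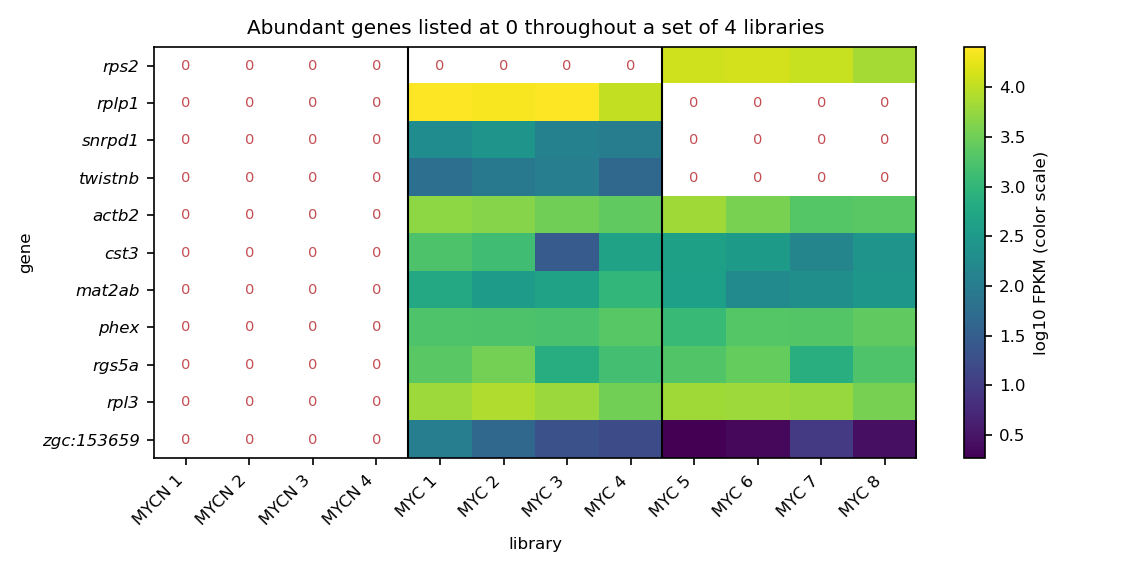
FPKM in each library of the 11 abundant genes whose zeros fill whole sets of 4 libraries, as colour on a log10 scale, with values of 0 left white and printed. Zeros cover all MYCN libraries for each gene, and also MYC 5 to 8 or MYC 1 to 4 for some, such as rplp1 and rps2.

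Across the 9606 genes tested, 1287 were called, 554 higher and 733 lower in MYC, and 385 and 420 of these had a log2 fold change beyond 1 in size. Among all genes tested, 9.33% had groups whose ranges did not overlap, where chance gives 0.404% of genes for 4 against 8 libraries. Without single libraries the total was 813 (MYCN 1), 815 (MYCN 2) and 707 (MYCN 4). MYCN against MYC 1 to 4 alone called 912 and against MYC 5 to 8 alone 850, and the replicate block over the first of these called 2261. Of the other genes named with a call, il7r, mych, tfap2a, apaf1, crabp1b, cirh1a, ltv1 and mbpb were not called against MYC 1 to 4 alone. Those not called against MYC 5 to 8 alone were plk4, ect2, cox5b2, mcl1b, sms and sat1a.1, and mhc1uba and rxraa were called against neither set. The share of calls that were higher was 43%, and 29.1% when each library was rescaled to the same sum, a step that moved the median log2 fold change of all genes from -0.05 to -0.22.

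On average, libraries of the same genotype resembled each other more than libraries of different genotypes. The mean Pearson correlation across genes was 0.937 within and 0.888 between genotypes. The difference was 0.0483, and the exact one-sided permutation p was 0.00202, the smallest that the arrangements can give. That test ignores the numbered pairs, and if labels are only swapped within pairs, the 16 arrangements gave an exact one-sided permutation p of 0.0625. This is the smallest they can give, so the threshold is out of reach, and this test was chosen only after the result was seen. Not every pair of libraries followed the average, as MYCN 3 correlated with MYC 3 at 0.926 and with MYCN 1 and MYCN 2 at 0.923 each. The first principal component (31.8% of the variance) placed the MYCN libraries at 43.2 to 54.5 and the MYC libraries at -29.8 to -18.2. The second (25.4%) set apart MYCN 3, MYC 3 and MYC 7, which lay at -45.8, -53.9 and -45.2. The third (12.4%) placed MYC 1 to 4 at 16.1 to 42.4 and MYC 5 to 8 at -29.7 to -20.4. The components and correlations included the 16 genes listed at 0 in a whole set and were not computed without them. Among the MYC libraries, the deviations of MYCN 3 from its group mean correlated best with those of MYC 3 (0.535) and MYC 7 (0.456). What MYCN 3, MYC 3 and MYC 7 share is not in the labels. The main fit treats all 12 libraries as independent, and the replicate block covered replicates 1 to 4 only.

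**Figure D4:**
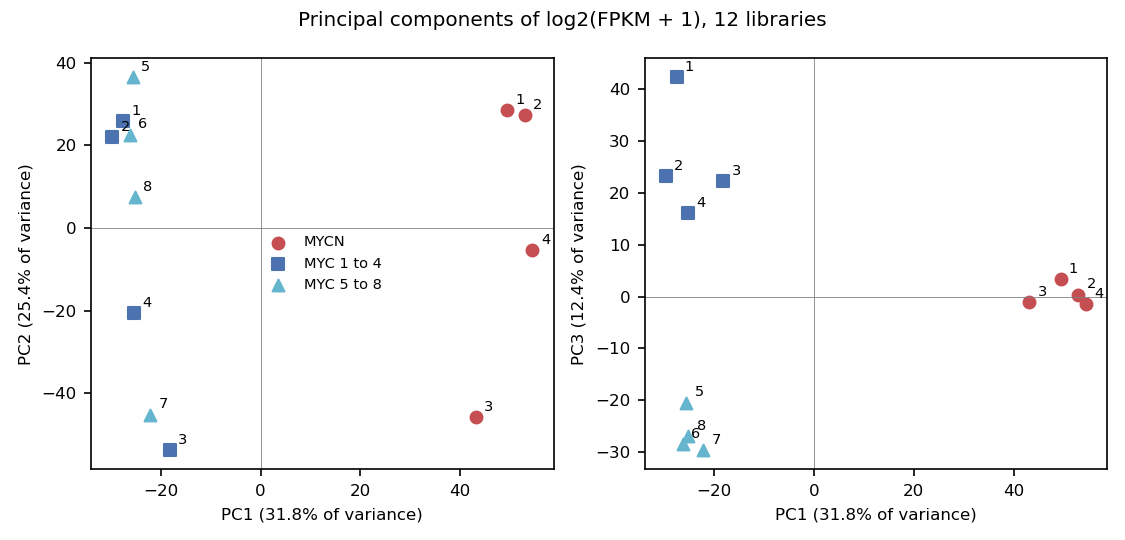
Principal components of log2(FPKM + 1) over the tested genes, 1 point per library, numbered by replicate. MYCN and MYC separate on the first component, and MYC 1 to 4 separate from MYC 5 to 8 on the third.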

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

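The tests of the zeros and of a smaller tumour cell share were chosen only after the result was seen. The difference between the genotypes is not one that chance splits of the libraries gave: of 100 splits into 4 and 8, 1 gave as many called genes, the real one with 1287, and the highest other gave 16. Among the 16 splits that part all 4 numbered pairs, 1 gave as many, and the highest other, with 90, set MYC 1 to 4 against the rest. All MYCN libraries lie in a set of their own, so neither kind of split can tell a difference of genotype from one of set.

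Abundant genes were listed at 0 in every MYCN library, among them 4 genes that every cell uses, the ribosomal protein genes rpl3, rplp1 and rps2 and the actin gene actb2, of 86 such genes measured. Loss of expression in MYCN tumours is argued against by these 4 genes, since growing cells need their products and 2 of them were also at 0 in a MYC set, rplp1 in MYC 5 to 8 and rps2 in MYC 1 to 4. For 11 of 16 abundant genes with any zero (68.75%), the zeros filled whole sets of 4 libraries. A step that failed per set when the values were made could give this. Abundant meant at least 100 FPKM in some library, so a gene at 0 in all 12 libraries was not counted. The elongation factor gene eef1a1l1 was at 0 in all 12, and whether its values failed was not tested. Cufflinks can set a locus with too many fragments to 0, which is a candidate cause that the FPKM values cannot test. The differences called for these genes may therefore say nothing about the tumours.

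Macrophage markers were higher in the MYC libraries, in cells that were sorted for EGFP. A larger macrophage share in the MYC sorts may account for it: the macrophage and pan-leukocyte scores, which share 0 genes, moved together within the genotypes (Pearson r = 0.927, permutation p = 0.00013, Spearman rho = 0.818, permutation p = 0.00343, 12 libraries, and r = 0.863 without the 2 libraries farthest from the median). Within the 8 MYC libraries alone r was 0.931 (exact permutation p = 0.00565) and rho 0.762 (exact permutation p = 0.0368). Scores were not centred by set, so the shift of both between the MYC sets (-1.01 and -0.903) enters these values. In MYCN and in MYC 1 to 4 the same libraries were highest and lowest by both scores. In MYC 5 to 8 the scores ran apart, with MYC 6 lowest for macrophages (-0.351) and highest for pan-leukocytes (0.145). There MYC 7 was the reverse (0.219 and -0.0573), so the link was not seen within that set. A smaller tumour cell share with all other cells alike would raise the markers of every other cell type alike. The macrophage score rose by more than the fibroblast (1.61), T and NK cell (1.14) and epidermal scores (1.04) among 12 other cell types (adjusted exact permutation p = 0.0242 each). The fibroblast difference was 1.35 without thy1 (exact permutation p = 0.0101). The other 9 of the 12 missed the threshold (adjusted exact permutation p = 0.15 to 0.188). These permutations ignored the numbered pairs, and the 16 swaps within pairs cannot reach the threshold. Macrophage markers also had the highest median of all lists (1.78), which favours a larger rise than other lists. The values therefore argue only weakly against such a share. Macrophages that had taken up tumour material, and expression of these genes by the tumour cells, stay open as untested.

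The melanocyte factor mitfa was present in all MYCN libraries and near 0 in all MYC libraries. Pigment cells in the MYCN sorts are argued against: the median log2 fold change of the 17 measured pigment genes was 0.026, all 5 that could be tested lay above 0 (median 0.56, range 0.18 to 1.51), and 10 of the 17 stayed under 1 FPKM in every MYCN library. The nearest 10 tested genes on the chromosome held 0 called ones, placed by the gene order of the GRCz12tu assembly. A mutant mitfa allele in the fish of the MYC group, as pigment mutant lines carry, and control of mitfa by the oncogene stay open as untested, and either could give this value.

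Some values lay far from the other libraries of their group, 17 of 346 groups checked, where chance gives about 1 in 20. In MYCN 3, cox6a2 stood at 97.7 FPKM (others 2.79 to 5.16), casq1b at 4.41 (0.180 to 0.367), mbpb at 7.78 (14.1 to 15.7) and mhc1uba at 12.4 (43.8 to 48.7). In MYCN 4, isl1 stood at 79.5 FPKM (31.2 to 36.3) and the kidney tubule score at 0.333 (-0.520 to -0.424). In MYCN 2, crabp1b stood at 21.8 FPKM (36.5 to 39.5), and in MYCN 1 the germ cell score at 1.19 (-0.699 to -0.512). In MYC 5, gulp1a stood at 2.72 FPKM (0.0186 to 0.630) and ttr at 6.74 (1.04 to 2.52). In MYC 1, col1a1b stood at 1.70 FPKM (0.171 to 0.606) and meis2a at 42.6 (17.8 to 25.3). In MYC 3, nadl1.2 stood at 8.99 FPKM (4.38 to 5.82) and the neutrophil score at -0.957 (0.162 to 0.592). In MYC 7, ect2 stood at 16.6 FPKM (0.250 to 2.22) and the neuronal score at -1.11 (-0.284 to 0.318), and in MYC 8 krt8 stood at 42.3 FPKM (8.27 to 16.9). No cause was tested for these.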

How the results depend on the processing

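The tests without genes listed at 0 in a set, of MYCN against MYC 5 to 8, with 3 groups and without MYCN 3, MYC 3 and MYC 7 were chosen only after the result was seen. Of the 129 called genes followed, none reversed under any alternative run, and 60 missed the threshold under at least 1, most often without MYCN 4 (40 genes) or by the exact rank-sum test (42 genes). Of the 1287 called genes, 804 were also called by the exact rank-sum test and 1155 with the replicate block. These 804 were the called genes whose group ranges did not overlap. At these group sizes no gene with overlapping ranges passed the rank-sum test, so the 42 misses there show only that ranges overlapped. The total moved beyond 1.5 times its value with library weights (1978, of which 929 higher) and with the replicate block over replicates 1 to 4 (2261, of which 984 higher and 1277 lower). It fell beyond that ratio for MYCN against MYC 5 to 8 (850, of which 454 lower) and without MYCN 1 (813), MYCN 2 (815) or MYCN 4 (707). The rank-sum test called 358 genes higher, and the 8 libraries of replicates 1 to 4 without a block called 451 lower, with fewer libraries in the fit. Leaving out each library in turn gave totals of 707 to 1346, with 289 to 628 higher and 418 to 723 lower. For the weights, the block and the left-out libraries the cause was not tested.

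Of the lists, 15 were called, and 8 after quantile normalisation, 7 by fry (5 of the 15, and the neural crest and fibroblast lists, since fry tests a list against no change and not against other genes), 2 by the exact permutation of the list score (pan-leukocyte and glycolysis, adjusted p = 0.0364 each) and 0 by camera with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Filters, weights or other library choices also ended calls: no filter for interferon, neuronal and translation (0.0520 each), 5 FPKM or more for mitosis (0.319), exocrine (0.135) and neuronal (0.0613), a pseudocount of 5 (0.0752) and weights (0.0675) for mitosis, 3 groups for translation (0.0552), and no MYCN 3, MYC 3 and MYC 7 for neuronal (0.0617), mitosis (0.0590) and exocrine (0.0544). Apart from the other list tests, 8 of the 15 missed the threshold under at least 1 alternative. The replicate block ended the calls of oxidative phosphorylation, Polycomb regulators, the neuronal list, the exocrine list and translation, gave one to the immediate early list, and changed no other list call except mitosis. It ended the calls of 7 named genes (apoa2, cycsb, klf2a, lect2l, pdip5, phlda3 and sparc) and gave one to 4 (cenpe, phox2a, rps26l and rsad2). The direction of 2 called lists turned: cytosolic ribosomal proteins after quantile normalisation (adjusted p = 0.832), and mitosis with the block (0.658) and for replicates 1 to 4 without it (0.882).

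The other reversals were in results with no call, and the cause was not tested for any of them. For rarga the log2 fold change was 0.0048 with a pseudocount of 5, 0.0379 after median-ratio scaling, 0.0709 after quantile normalisation, 0.126 for replicates 1 to 4 with and without the block, 0.0531 without MYCN 3, MYC 3 and MYC 7, and -0.0912 to 0.0928 over the left-out libraries. For myca it was -0.18 against MYC 5 to 8. Among the lists, the adjusted p after the turn was 0.941 for germ cells without the filter and 0.768 for T and NK cells at 5 FPKM or more. After quantile normalisation it was 0.926 for the MYC family and 0.880 for nucleotide synthesis, which also turned when rescaled to 1 sum (0.926). With the block it was 0.922 for the MYC family, 0.520 for mesenchymal markers and 0.658 for nucleotide synthesis, and without the block in those libraries 0.910, 0.529 and 0.841. Against MYC 5 to 8 it was 0.411 for T and NK cells, 0.976 each for the epidermal, germ cell and muscle lists and 0.184 for the immediate early list. By fry it was 0.892 for Schwann cells and 0.889 for nucleotide synthesis, and by exact permutation 0.842 for the latter. Among fits without 1 library, the direction turned without MYCN 1 for Schwann cells, without MYCN 2 (0.772) and MYCN 4 (0.959) for nucleotide synthesis and without MYC 1 for muscle. Over all such fits, turned or not, the adjusted p ran from 0.665 to 0.953 for Schwann cells, from 0.439 to 0.972 for nucleotide synthesis and from 0.396 to 0.860 for muscle.

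The library structure kept its direction and, over all arrangements, its exact p under the threshold, with a difference of 0.0461 to 0.0514 over the left-out libraries. A count-based tool was not run, since the values are FPKM, and a stricter threshold on the authors' own test was not run, since no such test was in the table used here. On simulated data with these group sizes and independent genes, the fit called 6 unchanged genes among 136 calls. It recovered 43% of changes of 1 and 87% of changes of 2 on the log2 scale. With 136 calls there and 1287 in the real fit, the adjustment was stricter on the simulated data. The shares recovered therefore do not give the power of the real fit, though smaller changes can stay below its threshold.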

Other observations

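The tests on immediate early genes and on macrophage markers between the MYC sets were chosen only after the result was seen. In MYC cells, several stress and hypoxia genes were higher while their lists as wholes were not called. Of 17 hypoxia genes 4 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.0669, and 0.0445 without MYC 1, 0.0479 without MYC 6, 0.0363 after rescaling to a common sum and 0.0265 against MYC 1 to 4). They were led by ankrd37, from 8.83 ± 1.44 to 38.4 ± 14.3 FPKM, and p4ha1b, a collagen prolyl hydroxylase, from 2.40 to 13.6 FPKM. Of 33 heat shock and unfolded protein genes 3 rose and 1 fell (list adjusted p = 0.497). The small heat shock gene hspb1 went from 2.2 to 8.23 FPKM and the stress factor ddit3 from 24 to 113 FPKM. Of 10 polyamine genes 1 rose and 1 fell (list adjusted p = 0.718). The spermine synthase gene sms went from 71.3 to 33.6 FPKM (adjusted p = 0.0137, and 0.0557 without MYCN 1). The gene sat1a.1, which acetylates polyamines, went from 10.5 to 29.0 FPKM (adjusted p = 0.0159, and 0.0614 and 0.0504 without MYCN 2 and MYCN 4).

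Other cell types gave mixed members. Of 12 neutrophil and granulocyte markers 2 rose and 1 fell (list adjusted p = 0.103, and 0.0369 without MYC 3, 0.0277 against MYC 5 to 8 and 0.0415 without MYCN 3, MYC 3 and MYC 7). The metalloprotease gene adam8a fell from 367 ± 31.2 to 61.3 ± 38.8 FPKM (-2.84 ± 0.45, adjusted p = 0.00135). Of 7 fibroblast, matrix and pericyte markers 3 fell and 1 rose (list adjusted p = 0.220, and 0.0138 by fry). The collagen gene col1a1b fell by 1.51 and mgp, an inhibitor of calcification, rose by 1.60 on the log2 scale. Of 4 B cell markers 2 rose (list adjusted p = 0.203, and 0.0180 with no filter), and of 12 T and NK cell markers il7r fell (-2.08, list adjusted p = 0.672, and 0.0274 against MYC 1 to 4 with a test pointing up). Of 6 Schwann cell and glial markers fabp7a fell (-1.48) and mbpb, of myelin, rose (1.36, adjusted p = 0.0157, and 0.0519 without MYCN 3; list adjusted p = 0.781). Of 12 epidermal markers 3 rose (list adjusted p = 0.341, and 0.0277 against MYC 1 to 4 and 0.0427 with a filter of 5 FPKM), led by the keratin zgc:77517 (1.79), and of 12 erythroid and thrombocyte markers 2 rose (list adjusted p = 0.687). No member passed among 6 interrenal (list adjusted p = 0.155, and 0.0322 against MYC 1 to 4 and 0.0499 after rescaling to a common sum), 4 kidney tubule (0.499), 9 muscle and heart (0.592), 4 germ cell (0.635) and 6 mesenchymal-type neuroblastoma markers (0.742). Test and median differed in sign for the epidermal (median -0.19, mean 0.20, test up), erythroid (-0.01, -0.12, up) and Schwann lists (-0.03, 0.05, up).

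The 8 MYC libraries split into MYC 1 to 4 and MYC 5 to 8. Between them 44 genes were called, 34 lower and 10 higher in MYC 5 to 8. Of the 35 splits of these libraries into 4 and 4, 1 gave as many, the real one, while the highest other gave 20. After median-ratio scaling without the genes listed at 0, 54 genes were called. That step removed 9 of the 44, and 33 of the other 35 were called again. Of the 36 lists, 13 were called between the sets, 11 lower and 2 higher in MYC 5 to 8. Lowest in adjusted p were the immediate early and dissociation response list (median -1.78, adjusted p = 6.03e-35) and the macrophage markers (median -1.19, adjusted p = 9.60e-22). Next came mitosis (median -0.78, adjusted p = 2.74e-13), pan-leukocyte markers (-1.11, 9.47e-11), T and NK cell markers (-1.01, 5.64e-09), and epidermal markers (-0.56) and the interferon response (-0.34, both 3.61e-05). Also lower were the mesenchymal-type, sympathoadrenal, retinoic acid and neural crest lists, and the 2 higher ones were oxidative phosphorylation and translation. The mean standardised scores differed by -1.46 for the immediate early list, -1.01 for macrophages, -0.903 for pan-leukocyte, -1.04 for T and NK cell, -0.783 for epidermal and -0.851 for mesenchymal-type markers. Each of these had an exact permutation p of 0.0286, the smallest that 70 arrangements can give. These p-values were not adjusted over the lists, so none of them is a call. The other 7 of the 13 were above 0.05 even so (exact permutation p = 0.143 for mitosis and oxidative phosphorylation, 0.171 for interferon, 0.229 for sympathoadrenal, 0.314 for translation, 0.343 for neural crest and 0.400 for retinoic acid). The calls of the 13 lists therefore rest on the list test at the preset correlation alone. Between the genotypes, 4 of 27 immediate early genes rose and 1 fell (list adjusted p = 0.0982, adjusted p = 0.837 with an estimated correlation), with atf3 going from 1.11 to 11.2 FPKM. At the preset correlation, the list was called up with the replicate block (adjusted p = 2.32e-07), against MYC 1 to 4 (1.33e-08), and without MYCN 2 (0.0388), MYCN 4 (0.0391), MYC 5 (0.0456), MYC 7 (0.0401) or MYC 8 (0.0205), and after rescaling to a common sum (0.0318).

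A strain difference between the fish of the genotypes could place called genes side by side on the chromosomes. Of 1250 called genes placed by the GRCz12tu gene order, 237 (19.0%) lay beside a called gene of the same direction, against a median of 164.0 and a highest of 211 in 1000 random draws (permutation p = 0.001, the smallest these draws can give). The count was 223 against 159.0 without neighbours of like name. The same number of genes ranked by the difference between the MYC sets gave 241 against 163.0 (permutation p = 0.001), so neighbours share changes there too, at 1.48 times the random median against 1.45 times between the genotypes. A strain difference and shared regulation of neighbours therefore cannot be told apart by this test.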
